A study of Drosophila melanogaster with 16 samples.

How the data were processed

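The study measured transcript ratios on 2-colour arrays of long oligonucleotides in 2 Drosophila cell lines, DmD8 and Kc. Notch, a receptor that is cut and enters the nucleus when it is activated, was activated by exposing the cells for 30 minutes to 2 mM EDTA, a chelator of divalent metal ions. Control cells received the buffer without EDTA. In a further DmD8 experiment, activated cells were set against activated cells that had been kept overnight with 300 µM DFK-167, an inhibitor of the presenilin protease that cuts Notch. Per the labels, each experiment had 3 biological replicates and dye swaps, which gave 5 arrays in each DmD8 experiment and 6 in Kc. RNA was extracted with Trizol and copied from oligo-dT primers, and spots were quantified with Dapple, per the labels. Background correction, normalization, the filter on spots, the log base and the direction of the ratios are not given in the sources used here.

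The deposited values are 1 log ratio per probe and array for 17258 probes. The deposited values were taken as log2; per the labels they are ratios of the quantified spots of 2 dyes, and what else the authors did to them is not given in the sources used here. The log2 scale was taken from their range, which ran from -3.35 to 6.51. A natural log could not be excluded, so values are given as log ratios and not as folds. Values were present for 13353 to 15638 probes per array (77.4% to 90.6%), and array medians lay between -0.13 and 0.16, so the arrays had not all been centred on 0. The number of arrays limits the precision; the channel intensities are not part of the values used here.

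The 5 columns labelled as the DmD8 inhibitor experiment held the same values as the 5 columns labelled as the DmD8 control experiment. Of 71019 pairs of values, 24 were not identical, by at most 4.87e-08, and all 24 were under 0.0001 in size. The 5 DmD8 arrays were therefore counted once, which left 11 distinct arrays out of 16. Which of the 2 DmD8 experiments they belong to is not settled by the labels. The other RNA on them is called the comparison RNA, which was from control cells by one set of labels and from inhibitor-treated cells by the other. The planned fit of 16 arrays became a fit of 11, and the planned test of the difference between the DmD8 experiments, and their overlap, could not be made.

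Replicates 1 to 3 had activated RNA in Cy5 per the labels, and replicates 4 and above were dye swaps. The rule set before the data were examined was to turn the sign of the swaps unless arrays of opposite dye correlated positively, and it was of little use: the mean correlation between opposite orientations was -0.03 in DmD8 and 0.01 in Kc, against 0.54 and 0.61 within an orientation. Read to the letter, it would have turned the swaps of DmD8 and not those of Kc, on correlations near 0. In both lines the swaps were instead taken as already turned by the authors, a departure from the rule made after seeing the values. The correlations between arrays were taken over 10060 genes and unnamed probes with a value on every array. Across all 12952 tested genes and unnamed probes, the part that changes sign with the dye correlated at 0.746 between DmD8 and Kc. The mean of the orientations correlated at -0.00315. A property of the probes would give this, but so would a response shared by the lines if the swaps had not been turned. These correlations are across genes, which are not independent replicates. E(spl)mbeta-HLH lay between 4.55 and 6.51 on all 6 Kc arrays. On the other side, of the 50 largest means over the arrays with activated RNA in Cy5, 39 kept their sign over the swaps in DmD8 but 12 in Kc. A positive value is called a rise on activation. That direction is likely and not stated: it rests on the order of the dyes in the labels and on E(spl) genes being known targets that Notch switches on.

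Probes were named from the platform annotation: 12658 probes had 1 gene symbol, 96 had several and 4504 were unnamed. Gene IDs of 12012 probes matched the RefSeq gene table of Drosophila, which changed no symbol. Probes of 1 gene were averaged (436 genes had more than 1 probe). Features, meaning named genes or single unnamed probes, entered the test if each experiment had at least 3 arrays with a value and both dye orientations. This left 12952 features, 8841 of them named genes.

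limma 3.58.1 in R 4.3.3 was fitted to the log ratios of the 11 arrays, with a mean and a dye term per experiment, and P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors are standard errors of this fit unless an SD is named, n is 5 arrays for DmD8 and 6 for Kc unless stated, which is above the 3 biological replicates per experiment, and figures were drawn with matplotlib 3.10.9. With 3 biological replicates per experiment, the dye swaps are read as repeats of their RNA, although the sample titles number the swaps on as replicates; which replicate a swap repeats is not stated. Deviations from the orientation mean correlated between swap n + 3 and replicate n (0.29 and 0.29 in DmD8; 0.54, 0.40 and 0.33 in Kc), whereas the other pairs lay between -0.34 and 0.06. Swaps read as technical repeats make the P values and standard errors over arrays too small, those of the gene list tests included. Counts over all features, of named genes and of gene list members are therefore given also with swaps averaged with a replicate under each of 6 pairings per experiment, taking the largest P for each gene ("under every pairing").

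The script was tested on simulated data in which 200 of 12952 features were changed. With swaps made to share the RNA of their replicate, 11.0% of calls over arrays were false in DmD8 and 19.3% in Kc, against 4.23% and 7.55% under every pairing. With independent arrays 2.40% and 6.84% of calls over arrays were false in DmD8 and Kc. With shared RNA and each swap averaged with its true replicate, 9.43% and 16.6% were false. The false share over arrays was thus higher with shared RNA, and averaging the true pairs lowered it only in part. Each setting had a single run, so small gaps between these shares cannot be read. The correlation of swap and replicate was set to 0.42 in both lines, the value of Kc, whereas it was 0.29 in DmD8. The shares hold for these settings only. In DmD8, 46.3% of features changed by 0.5 and 97.0% of those changed by 1 were recovered over arrays, against 13.4% and 91.0% under every pairing. In Kc it was 77.6% and 94.0% over arrays, against 26.9% and 94.0%. Small changes are thus mostly missed under every pairing.

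Genes were named by a rule fixed before the data were examined. It took every measured member of the 2 lists of E(spl) and Bearded genes, the 10 largest rises and 10 largest falls with the same sign on every array, and from each other list the 2 members past the threshold with the largest change. For the difference between the lines it took the 5 largest in each direction. The 25 gene lists were also fixed beforehand and cover the Notch and other signalling pathways, stress, cell cycle, death, metabolism, ribosomes, and markers of muscle, blood, wing disc, neural and fat body cells. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists and comparisons, then with an estimated correlation on features measured on every array, and with fry. After the data were seen, the same 3 tests were run with swaps averaged, taking the largest P of each list over the pairings. Overlaps were tested with Fisher's exact test, two-sided, adjusted over the 4 combinations of direction. Alternatives covered centring, scaling, the filter, the dye term, the fit of each experiment alone, the unit of replication, the arrays used, a block for the replicate number, single probes, eBayes and the threshold. Genes not named in the text were not all tested; several E(spl) and Bearded genes had too few values or are not analysed here.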

Results

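The data comprised 11 distinct arrays, 5 of DmD8 cells, a Drosophila line, and 6 of Kc cells, another Drosophila line. Each array set RNA from cells with activated Notch against a comparison RNA. For Kc the comparison was RNA from control cells. For DmD8 the same values carried the labels of both experiments, activated against control and activated against inhibitor-treated cells, so the comparison RNA is one of these. Each array gave ratios for 13353 to 15638 of 17258 probes. Each experiment had 3 biological replicates, and the dye swaps are read as repeats of their RNA, so P values and standard errors over arrays are too small. Counts under every pairing, with swaps averaged with a replicate in each possible way, allow for this.

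The DmD8 arrays ask which transcripts differ between cells with Notch activated by 30 minutes of EDTA and the comparison cells. By the control labels the ratios hold any effect of EDTA besides that on Notch. By the inhibitor labels they hold any effect of the overnight drug. Of 8 tested genes of the E(spl) complex and Bearded family, which encode basic helix-loop-helix (bHLH) repressors and small proteins known to be switched on by Notch, 6 rose, and 3 of them under every pairing. Of 4 tested bHLH members 3 rose: E(spl)mdelta-HLH by 1.26 ± 0.13, E(spl)m7-HLH by 1.25 ± 0.16 and E(spl)m3-HLH by 1.24 ± 0.13 (limma, adjusted p = 0.000211, 0.000625 and 0.000225), all positive on 5 of 5 arrays. E(spl)mbeta-HLH stood at 0.04 ± 0.26 (adjusted p = 0.951). Of 4 tested members outside the bHLH class, E(spl)m2-BFM (1.34 ± 0.19), E(spl)malpha-BFM (1.14 ± 0.19) and E(spl)m6-BFM (1.14 ± 0.17) rose, and Tom stood at 0.04 ± 0.25 on 4 arrays. The bHLH list had a median of 1.25 and passed camera (adjusted p = 2.54e-09; adjusted p = 0.0657 with an estimated correlation). The other list had a median of 1.14 (adjusted p = 1.11e-05) and too few complete members for an estimated correlation. Adjusted over the list alone, 3 members rose in each. The sign of the ratios was itself taken in part from these genes, so their direction is not independent evidence. Of 7 bHLH members on the list 5 were among the named genes of the array, and of 11 others 8. The named members left untested lacked the 3 values and both dye orientations that a gene needed in each line. In DmD8 E(spl)m5-HLH had a mean of 0.63 ± 0.22 (SD, n = 4 arrays), E(spl)m4-BFM 0.82 ± 0.21 (SD, n = 4), Ocho 0.03 ± 0.65 (SD, n = 4), Kaz-m1 -0.19 (n = 2) and Brd -0.33 (n = 1), and in Kc E(spl)m5-HLH 0.25 ± 0.22 (SD, n = 3), E(spl)m4-BFM 0.16 ± 0.28 (SD, n = 3), Kaz-m1 0.28 (n = 4) and Ocho -0.80 (n = 2).

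Among named genes outside the complex with the same sign on every array, the largest rises were those of Him, an inhibitor of muscle differentiation in progenitors (2.36 ± 0.28), Egfr, the EGF receptor (2.32 ± 0.15), and peb, a zinc finger transcription factor also called hindsight (2.10 ± 0.20). They were followed by drl, a Ryk-type receptor tyrosine kinase (1.80 ± 0.19), CG14275 (1.75 ± 0.17), aos, a secreted inhibitor of the EGF receptor (1.54 ± 0.19), Cph (1.51 ± 0.18), CBP (1.39 ± 0.13) and Reck (1.35 ± 0.21). Adjusted p for these genes lay between 7.47e-06 for Egfr and 0.00248 for Reck, and all were positive on 5 of 5 arrays. Of 14 tested EGF receptor pathway genes, 3 rose and none fell (5 adjusted over the list alone), and the list passed camera (median 0.10, adjusted p = 5.17e-05; adjusted p = 0.132 with an estimated correlation). Of 12 other reported Notch targets 2 rose, Him and kirre (0.53 ± 0.11), and 4 adjusted over the list alone (camera adjusted p = 0.00112; adjusted p = 0.0946 with an estimated correlation). Among 13 muscle genes 3 rose and 1 fell, with Him and twi, a mesodermal bHLH factor (1.06 ± 0.17), in front (camera adjusted p = 0.0113; adjusted p = 0.0946 with an estimated correlation). Of 17 cell cycle genes 5 rose, led by Cdk4 (0.38 ± 0.10) and CycE (0.35 ± 0.08), with a list median of 0.19 (camera adjusted p = 2.89e-05; adjusted p = 0.0946 with an estimated correlation). Single members of other lists rose as well: ptc, the Hedgehog receptor (1.14 ± 0.12), 1 of 9 Hedgehog pathway genes; neur, a ubiquitin ligase for Notch ligands (0.54 ± 0.10), 1 of 12 Notch pathway components; and nkd (0.39 ± 0.09), 1 of 2 tested Wingless pathway genes. Of 20 adhesion genes 3 rose and 1 fell, with the integrin subunit mew at 0.72 ± 0.08 and the cadherin shg at 0.50 ± 0.09.

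The lowest ratio was that of CG11893 (-2.35 ± 0.26), followed among named genes by the trehalose transporter Tret1-1 (-2.17 ± 0.11), Tret1-2 (-2.14 ± 0.11), Dgp-1 (-2.05 ± 0.08) and the cytochrome P450 genes Cyp6a20 (-1.99 ± 0.11) and Cyp6a23 (-1.78 ± 0.08). The activin-like ligand daw fell by 1.79 ± 0.13, 1 of 14 Dpp and activin pathway genes. The receptor subunit nAChRalpha1 (-1.75 ± 0.11), CG10365 (-1.54 ± 0.10) and MME1 (-1.52 ± 0.08) completed the 10 largest. Of 11 glycolysis genes the hexokinase Hex-A fell (-1.12 ± 0.09), and that list had a median of 0.04 and did not pass camera (adjusted p = 0.55). Of 13 heat shock proteins and chaperones 3 fell, with Hsc70-3, the chaperone of the endoplasmic reticulum, at -1.02 ± 0.08 and Hsc70-5 at -0.44 ± 0.09, and the list median was -0.24 (camera adjusted p = 0.00307; adjusted p = 0.324 with an estimated correlation). Of 10 immediate early and JNK response genes 2 fell, Gadd45 (-0.93 ± 0.13) and the Fos gene kay (-0.73 ± 0.12), and 1 rose. Of 14 immune and Toll genes 2 fell, the NF-kappaB factor dl (-0.72 ± 0.08) and its inhibitor cact (-0.31 ± 0.07). Of 10 insulin and growth genes scyl fell (-0.96 ± 0.16). Of 12 ecdysone response genes 2 rose and 2 fell, with Eip93F at 0.54 ± 0.13 and ImpL2 at -0.51 ± 0.11. The lists of cell death, metal response, blood cell, wing disc patterning, neural, fat body, JAK/STAT and ribosomal protein genes had no member past the threshold with limma; of their 100 members, 15 had an unadjusted p under 0.05. Adjusted over the list alone, the rises were 6 in cell cycle, 4 in muscle, 4 in adhesion, 4 in ecdysone, 1 in immune and 1 in fat body genes, and the falls 4 in heat shock, 3 in ecdysone and 3 in insulin genes; counts not named here were the same. Median and mean, or median and camera, had opposite signs in the cell death, JNK, wing disc, JAK/STAT and glycolysis lists, none of which passed camera.

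Under every pairing fewer list members stayed past the threshold in DmD8: 2 of the E(spl) bHLH list, 1 of the other E(spl) and Bearded list, 1 rise and 1 fall in the JNK list, 1 rise each in the EGF receptor, adhesion, muscle and Hedgehog lists, and 1 fall each in the heat shock, immune, Dpp and glycolysis lists. The cell cycle, other Notch target, Notch pathway, Wingless, ecdysone and insulin lists kept none with limma, and 22 of their 65 members had an unadjusted p under 0.05 there. With swaps averaged, camera at the preset correlation lost the EGF receptor and muscle lists (adjusted p = 0.0854 and 0.0813) and kept the other 5.

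In all, 938 of 12952 features differed in DmD8, 399 higher and 539 lower, and 89 under every pairing, 28 higher and 61 lower. Of 44 named genes past the threshold, 23 stayed past it under every pairing, among them Egfr, peb, E(spl)m2-BFM, E(spl)m3-HLH, E(spl)m7-HLH and ptc, whereas Him, aos and drl (adjusted p = 0.0795, 0.113 and 0.0628) and E(spl)mdelta-HLH, E(spl)m6-BFM and E(spl)malpha-BFM (adjusted p = 0.0627, 0.0844 and 0.0636) did not. The higher share was 42.5%, and 54.7% after each array was centred on its median; with the swaps turned it was 44.9%. The count was 610, 591, 406 and 547 without array 1, 2, 4 or 5.

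**Figure D1:**
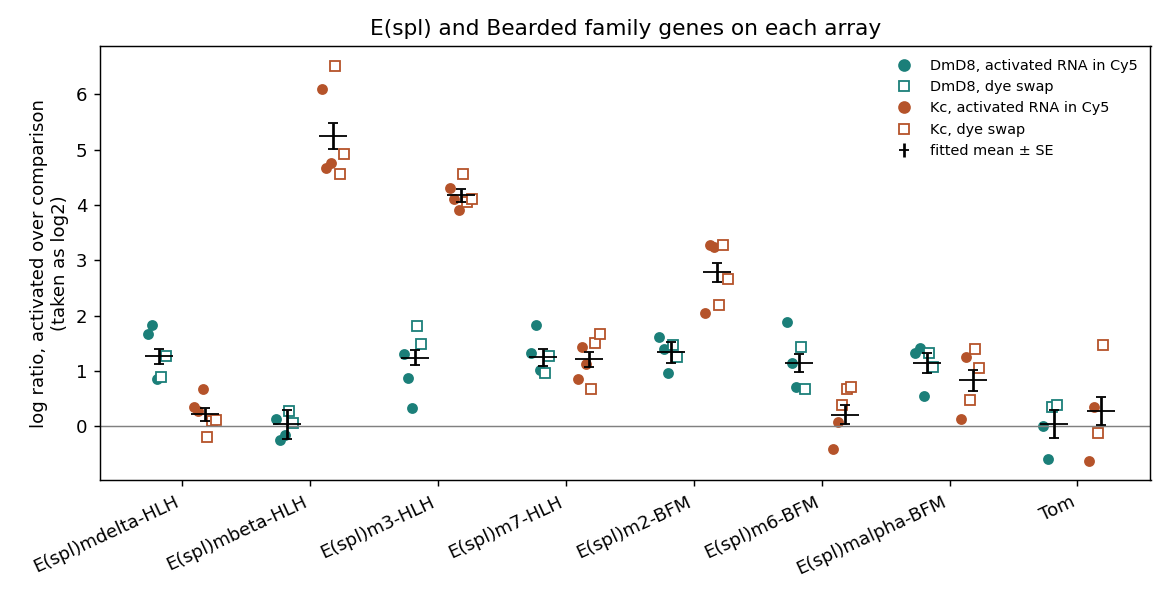
Log ratio of activated over comparison RNA (y axis, taken as log2) for 8 E(spl) and Bearded family genes, with 1 point per array, filled circles for arrays with activated RNA in Cy5, open squares for dye swaps, and bars for the fitted mean ± SE. E(spl)mbeta-HLH lies between 4.55 and 6.51 on the 6 Kc arrays and between -0.26 and 0.27 on the 5 DmD8 arrays, whereas E(spl)m7-HLH is above 0 on every array of both lines.

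The Kc arrays ask the same of another cell line, against control cells, so these ratios hold any effect of EDTA besides that on Notch. E(spl)mbeta-HLH (5.25 ± 0.23) and E(spl)m3-HLH (4.17 ± 0.12) had the largest ratios of the line, and E(spl)m2-BFM stood at 2.78 ± 0.17, E(spl)m7-HLH at 1.21 ± 0.14 and E(spl)malpha-BFM at 0.83 ± 0.19 (adjusted p from 5.18e-09 to 0.0154). E(spl)mdelta-HLH (0.22 ± 0.12, adjusted p = 0.301), E(spl)m6-BFM (0.21 ± 0.17) and Tom (0.27 ± 0.25) did not pass. Thus 3 of 4 bHLH members and 2 of 4 others rose, with the same counts adjusted over the list alone (camera adjusted p = 2.03e-41 and 5.17e-05; adjusted p = 0.0657 with an estimated correlation for the bHLH list). E(spl) genes had also served to choose the orientation, so the direction of these lists, and its hold over both dyes, is not independent evidence. Other large rises, each above that of E(spl)m7-HLH, were those of dysf, a bHLH-PAS factor (2.95 ± 0.11), CG14606 (2.89 ± 0.14), vri, a bZIP repressor of the circadian clock (2.28 ± 0.11), Ctns, the lysosomal cystine transporter (2.00 ± 0.08), CG12290 (1.67 ± 0.10), CG14961 (1.67 ± 0.09) and klu, a zinc finger factor (1.58 ± 0.08), each positive on 6 of 6 arrays.

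Of 12 other reported Notch targets 5 rose, with klu and the repressor zfh1 (0.77 ± 0.09) in front (camera adjusted p = 1.11e-05; adjusted p = 0.0657 with an estimated correlation). Of 10 immediate early and JNK response genes 5 rose, among them puc, the phosphatase that limits JNK (0.76 ± 0.09), and 1 fell, the zinc finger gene cbt (-1.17 ± 0.19) (camera adjusted p = 0.00302; adjusted p = 0.0946 with an estimated correlation). Of 14 blood cell genes 4 rose, including zfh1 and the GATA cofactor ush (0.74 ± 0.08) (camera adjusted p = 0.00307; adjusted p = 0.0946 with an estimated correlation). Of 6 JAK/STAT genes 3 rose, among them ken (0.51 ± 0.07) and chinmo (0.48 ± 0.12) (camera adjusted p = 0.00679; adjusted p = 0.197 with an estimated correlation). Of 12 ecdysone response genes 5 rose and 1 fell, with br at 0.62 ± 0.06 and Eip93F at 0.53 ± 0.14 on 4 arrays (camera adjusted p = 0.0142; adjusted p = 0.0946 with an estimated correlation). Of 10 insulin and growth genes 3 rose, including the receptor InR (0.62 ± 0.10) and Sesn (0.51 ± 0.09) (camera adjusted p = 0.00441; adjusted p = 0.0946 with an estimated correlation).

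Other lists did not pass camera in Kc, though single members did. In the Dpp and activin list 4 of 14 rose and 1 fell, led by the receptor wit (0.99 ± 0.10) and shn (0.78 ± 0.14). Toll and immune genes rose in 4 and fell in 1 of 14 cases, with cact at 0.62 ± 0.07 and the Toll ligand spz at 0.46 ± 0.11. Adhesion genes rose in 6 of 20 cases, with LanA at 0.69 ± 0.13 and mew at 0.37 ± 0.08. Among 12 Notch pathway components 3 rose and 1 fell, with the coactivator mam at 0.58 ± 0.11 and the gamma-secretase subunit pen-2 at -0.37 ± 0.07. Among 14 EGF receptor pathway genes 3 rose and 1 fell, with the repressor aop at 0.68 ± 0.09 and the kinase Dsor1 at -0.45 ± 0.08. The glycolysis list held 2 rises in 11, Hex-A (0.85 ± 0.08) and sima (0.33 ± 0.08). Fat body genes held 2 in 6, the lipase bmm (0.65 ± 0.09) and Lsd-2 (0.37 ± 0.09). Cell death genes held 2 in 9, p53 (0.62 ± 0.16) and egr (0.31 ± 0.08). Muscle genes held 2 in 13, zfh1 and rst (0.56 ± 0.10), and ribosomal protein genes 3 in 39, with RpL27 at 0.41 ± 0.09 and RpL3 at 0.28 ± 0.07. The patterning gene tsh rose (0.60 ± 0.14, 1 of 10), ptc rose (0.56 ± 0.11) while ihog fell (-0.30 ± 0.08) among 9 Hedgehog genes, and the Cdc25 phosphatase twe fell (-0.52 ± 0.06, 1 of 17 cell cycle genes). Heat shock, metal response, neural and Wingless genes had no member past the threshold with limma, and 11 of their 31 members had an unadjusted p under 0.05. Of 13 heat shock genes 6 were higher on Kc arrays 2 and 5 than on the other 4, and the other 7 were not; the highest, Hsp26, stood at 1.90 and 1.92 on arrays 2 and 5, and between -0.27 and 0.14 on the other 4. The probes of near-identical Hsp70 genes may share signal. Adjusted over the list alone, the rises were 8 in adhesion, 6 in JNK, 6 in ecdysone, 5 in blood cell, 4 in Notch pathway, 4 in EGF receptor, 4 in JAK/STAT, 4 in insulin, 3 in cell death, 2 in Hedgehog and 2 in ribosomal protein genes. The falls became 2 in Dpp and 1 in other Notch targets, cell death and adhesion genes, and counts not named here were the same. Under every pairing 3 members stayed past the threshold in each of the E(spl) bHLH, other Notch target and blood cell lists, 2 rises and 1 fall in the JNK list, 2 in the ecdysone list, 1 rise and 1 fall in the Dpp list, and 1 each in the other E(spl) and Bearded, EGF receptor, cell cycle, muscle, immune and glycolysis lists. The adhesion, JAK/STAT, insulin, Notch pathway, cell death, wing disc, fat body, Hedgehog and ribosomal protein lists kept none with limma, and 30 of their 121 members had an unadjusted p under 0.05 there. With swaps averaged, camera at the preset correlation lost the JNK, JAK/STAT and ecdysone lists (adjusted p = 0.0635, 0.0613 and 0.0854) and kept the other 5. In the glycolysis list the median (-0.0123) and the mean (0.113) had opposite signs.

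The largest falls in Kc were smaller than the largest rises. Among named genes with the same sign on every array they were CG3348 (-1.20 ± 0.14), cbt, sofe (-1.13 ± 0.08), CG42724 (-1.07 ± 0.14), CG18135 (-1.05 ± 0.11), CCDC53 (-0.97 ± 0.13), TTLL4A (-0.93 ± 0.10), HemK1 (-0.91 ± 0.08), CG1239 (-0.91 ± 0.06) and, on 3 arrays, KaiR1D (-0.87 ± 0.11). In all 1542 features differed in Kc, 919 higher and 623 lower, and 234 under every pairing, 147 higher and 87 lower. The higher share was 59.6%, 51.4% after centring and 44.7% on the arrays with activated RNA in Cy5 alone and 35.3% with the swaps turned, so the excess of rises depended on the scaling, the arrays used and the orientation. Of 54 named genes past the threshold 30 stayed past it under every pairing, including mbeta, m3, m7, m2-BFM, dysf, vri and klu, whereas E(spl)malpha-BFM did not (adjusted p = 0.124). The count was 941 without array 4, and 899 without arrays 2 and 5, a setting chosen after the data were seen.

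**Figure D2:**
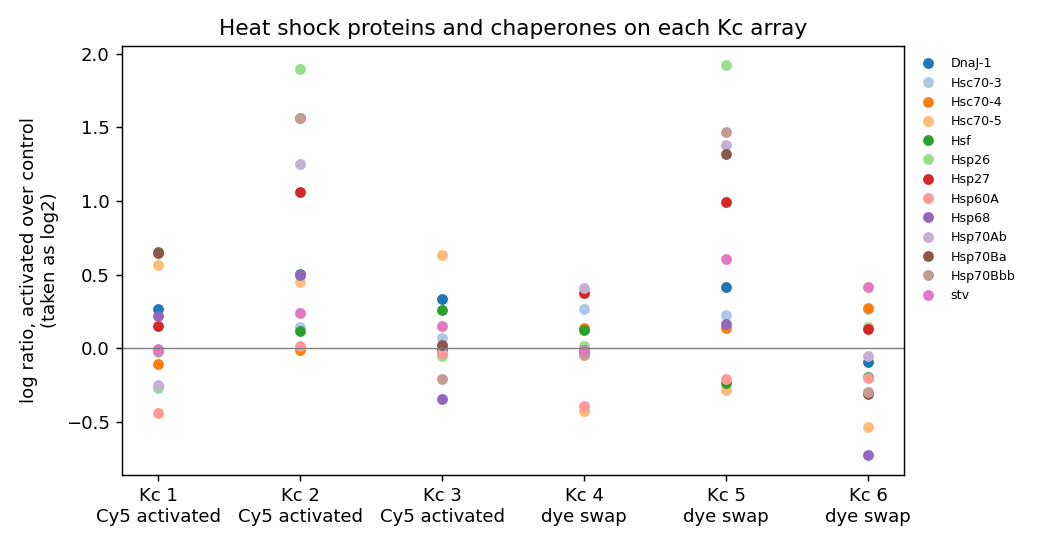
Log ratio of activated over control RNA (y axis, taken as log2) of 13 tested heat shock and chaperone genes on each of the 6 Kc arrays (x axis). Hsp26 stands at 1.90 on array 2 and 1.92 on array 5, and at most at 0.14 on the other 4 arrays.

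The comparison of the lines asks which ratios differ. Kc was set against control cells, and DmD8 against control or inhibitor-treated cells. A difference between the lines, here and below, may thus come from the cells or from the comparison RNA. The test of the difference called 1415 features, 572 higher in DmD8 and 843 lower, and 368 under every pairing. Above Kc stood Him (difference 2.41 ± 0.41), Egfr (2.11 ± 0.20), CG14275 (2.05 ± 0.24), CG42807 (1.99 ± 0.41) and CG18135 (1.88 ± 0.16). Below Kc stood E(spl)mbeta-HLH (-5.21 ± 0.35), E(spl)m3-HLH (-2.93 ± 0.18), CG14606 (-2.87 ± 0.21), dysf (-2.86 ± 0.17) and vri (-2.82 ± 0.17), which fell in DmD8 (-0.54, adjusted p = 0.0225). Of the 10, only Him and CG42807 were not past the threshold under every pairing (adjusted p = 0.0918 and 0.136). Within the E(spl) complex, E(spl)mdelta-HLH rose more in DmD8 by 1.05 ± 0.18 (adjusted p = 0.00389) and E(spl)m6-BFM by 0.93 ± 0.23 (adjusted p = 0.029), and E(spl)m2-BFM less by 1.44 (difference -1.44 ± 0.26, adjusted p = 0.00491). Under every pairing the genes higher in DmD8 lost their call (E(spl)mdelta-HLH adjusted p = 0.0626, E(spl)m6-BFM adjusted p = 0.132), and those lower in DmD8, E(spl)mbeta-HLH, E(spl)m3-HLH and E(spl)m2-BFM, kept it (adjusted p = 0.000818, 0.000818 and 0.0287). For E(spl)m7-HLH the difference was 0.04 ± 0.21 (adjusted p = 0.918). The higher share was 40.4%, and 56.0% after centring. The count was 765 without DmD8 array 4 and 871 without Kc arrays 2 and 5.

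Of the 25 gene lists, 6 differed between the lines by camera. Cell cycle genes stood higher in DmD8 (median difference 0.24, adjusted p = 5.17e-05; adjusted p = 0.0946 with an estimated correlation). The E(spl) bHLH list (-1.44, adjusted p = 6.32e-06; adjusted p = 0.236 with an estimated correlation) and heat shock genes (-0.50, adjusted p = 0.00132; adjusted p = 0.236 with an estimated correlation) stood lower, the latter with the 2 high Kc arrays in the comparison. Insulin and growth genes (-0.36, adjusted p = 0.0142), immune and Toll genes (-0.22, adjusted p = 0.0172) and Dpp and activin genes (-0.21, adjusted p = 0.0375) also stood lower, each with adjusted p = 0.132 with an estimated correlation. With swaps averaged, camera at the preset correlation kept the cell cycle and heat shock lists and lost the E(spl) bHLH, insulin, immune and Dpp lists (adjusted p = 0.312, 0.0508, 0.137 and 0.0996).

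Both lines shared 78 features that rose, against 28.3 from independent lists (odds ratio 3.38, 95% interval 2.58 to 4.39, Fisher's exact test, adjusted p = 3.5e-16). Among them were E(spl)m3-HLH, E(spl)m7-HLH, E(spl)m2-BFM, E(spl)malpha-BFM, peb, ptc, neur, aop, br, Mkp3 and emc. By the same exact test the overlap was also above chance for features lower in both (46 against 25.9, adjusted p = 0.000239). It was so for those lower in DmD8 and higher in Kc (82 against 38.2, adjusted p = 5.53e-11), which included Hex-A, vri, cact, kay and Gadd45. It was so too for those higher in DmD8 and lower in Kc (29 against 19.2, adjusted p = 0.0239). Both lines shared 1 estimate of the spread per feature, so features with a small spread can be called in both. The exact test does not allow for this, so these P values do not by themselves show a shared response. The fits under every pairing took each line alone. Under every pairing 5 features rose in both against 0.318 by chance (Fisher's exact test, adjusted p = 5.6e-05), namely E(spl)m2-BFM, E(spl)m3-HLH, E(spl)m7-HLH, Lime and MESR3. The E(spl) genes in these shared rises had served in part to choose the orientation, so their rise in both lines is not independent evidence. The other 3 overlaps were lost under every pairing by the same exact test: 3 features lower in DmD8 and higher in Kc against 0.692 by chance (adjusted p = 0.0639), 1 higher in DmD8 and lower in Kc against 0.188 (adjusted p = 0.23) and 0 lower in both against 0.41 (adjusted p = 1). Genes in these overlaps other than those of the naming rule were chosen after their values were seen.

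**Figure D3:**
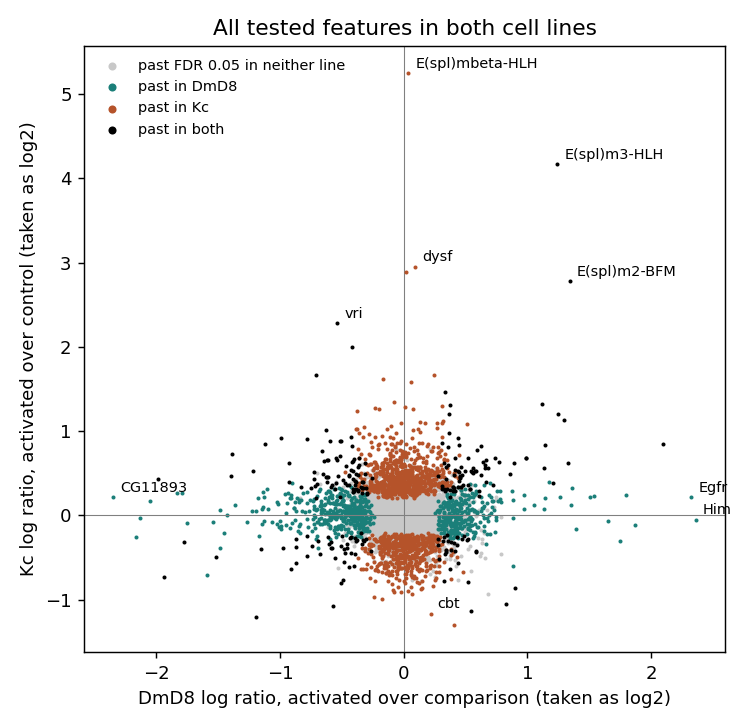
Log ratio in DmD8 (x axis) against log ratio in Kc (y axis), both taken as log2, for 12952 tested features, coloured by whether they passed the threshold of 0.05 in DmD8, Kc, both or neither. E(spl)mbeta-HLH lies at 0.04 in DmD8 and 5.25 in Kc, and Him at 2.36 in DmD8 and -0.05 in Kc.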

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

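Tests on the E(spl) differences and the heat shock genes were chosen only after those results were seen. The sign patterns and the splits of the arrays were set before, and the detoxification list before the values of its members were seen.

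The DmD8 values carry the labels of 2 experiments. If they come from the inhibitor experiment, detoxification genes may lie higher in the comparison RNA, which would have been kept overnight with the drug. In DmD8 the 24 tested members of such a list, which left out genes already seen, had a median of -0.14, with GstD1 (-0.87 ± 0.09), GstD3 (-0.73 ± 0.09) and Cyp6a9 (-0.32 ± 0.07) lower and none higher (camera in limma, adjusted p = 0.00469). In Kc, where no inhibitor was used, 4 members were higher and none lower (median 0.10, camera adjusted p = 0.00164), and the list differed between the lines (median -0.28, camera adjusted p = 3.84e-05). With an estimated correlation, a check added last on the 16 members with a value on every array, these calls held (adjusted p = 0.0333, 0.0223 and 0.0161, over the 6 tests of this list and the ER list alone). Under every pairing 1 of the 3 falls in DmD8 and 2 of the 4 rises in Kc stayed past the threshold. With swaps averaged the list calls held at the preset correlation and were lost with an estimated one (adjusted p = 0.279, 0.205 and 0.203). Cyp6a20 and Cyp6a23 were already among the largest falls in DmD8. GstD2, Cyp6d4 and Cyp4e2 were already among the features lower in DmD8 and higher in Kc, the direction the list then took. The list holds other Cyp6a and GstD genes, so it is not independent of values already seen. The result goes with the inhibitor experiment, but a DmD8 response to EDTA that differs from that of Kc stays open, so the labels remain unsettled.

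E(spl) genes rose by different amounts in the lines, with differences in DmD8 minus Kc of -5.21 for E(spl)mbeta-HLH, -2.93 for E(spl)m3-HLH, -1.44 for E(spl)m2-BFM, 1.05 for E(spl)mdelta-HLH and 0.93 for E(spl)m6-BFM. The last 2 differences lost their call under every pairing (adjusted p = 0.0626 and 0.132). After each array was centred and scaled alike the mdelta difference was 1.14 and the mbeta difference -5.23, both past the threshold. The differences thus do not rest on the centre or the scale of the arrays. Array medians lay between -0.13 and 0.16, so centring could hardly have removed differences of this size. The check cannot decide on other steps of the authors' normalization, which are not given. The largest dye coefficient of these 5 genes was 0.41, below the smallest difference of 0.93. The orientation of the swaps was chosen in part from E(spl) genes, so this cannot decide on dye bias. A spot too dim or too bright to give a ratio for mbeta in DmD8 stays open: all 5 arrays gave a ratio, and intensities are not part of the values. A biological difference between the lines is a hypothesis that stays open with it, and so does the comparison RNA in DmD8.

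Of 13 heat shock genes 6 were higher on Kc arrays 2 and 5, which carry opposite dyes, than on the other 4, and the other 7 were not. These arrays were picked because the genes were high there, so no chance value applies to that count. The lower of these 2 arrays stood 0.35 above the highest of the other 4 in list median relative to the array median, which argues against a fault of 1 array. The gap to the next array of the same orientation was at least 0.42, which argues against dye bias. A stress in 1 culture may have given it if array 5 repeats the RNA of array 2, which the labels do not say, and no biological explanation was tested.

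The DmD8 count of 938 was above the other 14 sign patterns that could be fitted, the highest of which gave 366 genes; with 15 patterns a share under 0.05 cannot be reached. In Kc 1542 was reached by 1 of 31 patterns, the real one, with 93 as the highest other. That count treats the arrays as independent. With each swap as a repeat of a replicate, 4 sign patterns remain in either line, too few for a share under 0.05, so Kc excludes random signs only for independent arrays. The pattern that follows the dyes could not be fitted with the dye term. Turning the swaps gave 2211 features in DmD8 and 2592 in Kc. A dye structure would give this, but so would a response shared by the lines if the authors had not turned the swaps. The counts cannot tell these apart. For the difference between the lines, 1 of 100 splits of the 11 arrays, the real one, gave 1415 features, and the highest other gave 36. This again holds for independent arrays; with swaps tied to replicates 10 splits remain, too few for a share under 0.05.

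Single arrays stood apart in 8 of 152 series of values, against 7.6 by chance. The gap of the array to its neighbour, as a share of the range, was 0.806 for drl and 0.765 for CG11893 in DmD8, on array 3 (0.71 against 1.89 to 2.18, and -0.48 against -3.01 to -2.42). It was 0.798 for CG14961 (array 1), 0.649 for CCDC53 (array 4) and 0.658 for tsh (array 4) in Kc. For list medians it was 0.742 for the EGF receptor pathway and 0.770 for JAK/STAT in DmD8 (array 3), and 0.781 for blood cell genes in Kc (array 2). Every case in DmD8 thus lay on array 3, whose SD of 0.33 was the lowest of the DmD8 arrays. The series share arrays, so the count against 7.6 does not show that these cases came by chance.

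Of 91 named genes 64 differed between the lines, 26 higher and 38 lower in DmD8, where the comparison RNA may differ from that of Kc. Over all features 1415 of 12952 differed. Many of the named genes were chosen for a large change in a line or between the lines, so a high share among them was built in. Under every pairing 37 of the 64 stayed past the threshold, 10 higher (Egfr, CG14275, CG18135, sofe, CBP, KaiR1D, TTLL4A, CG1239, HemK1 and twe) and 27 lower. The genes lower in DmD8 that lost the call were ken, ush, zfh1, puc, shn, wit, scyl, RpL3, Hsc70-5, RpL27 and CG11893. Beyond the E(spl) genes, the differences above 0 were 2.41 for Him, 2.11 for Egfr, 2.05 for CG14275, 1.99 for CG42807, 1.88 for CG18135, 1.68 for sofe, 1.56 for drl, 1.56 for CBP, 1.39 for cbt, 1.30 for aos, 1.28 for Cph, 1.24 for peb, 1.23 for Reck, 1.01 for KaiR1D, 1.00 for TTLL4A, 0.93 for twi, 0.89 for CG1239, 0.84 for HemK1, 0.72 for CCDC53, 0.68 for twe, 0.63 for Dsor1, 0.57 for ptc, 0.54 for pen-2 and 0.51 for Cdk4. Signalling and transcription genes lower in DmD8 were ken (-0.44), ush (-0.46), zfh1 (-0.53), puc (-0.68), shn (-0.81), ImpL2 (-0.82), Sesn (-0.85), wit (-0.86), cact (-0.93), dl (-1.06), kay (-1.16), scyl (-1.21), klu (-1.53), Gadd45 (-1.54), daw (-2.05), vri (-2.82) and dysf (-2.86). The others were RpL3 (-0.49), Hsc70-5 (-0.50), RpL27 (-0.52), MME1 (-1.02), Hsc70-3 (-1.18), CG12290 (-1.43), Cyp6a23 (-1.46), CG10365 (-1.47), nAChRalpha1 (-1.66), Tret1-1 (-1.91), Hex-A (-1.98), Tret1-2 (-2.10), Dgp-1 (-2.22), CG14961 (-2.38), Ctns (-2.41), Cyp6a20 (-2.42), CG11893 (-2.56) and CG14606 (-2.87). List medians differed by -1.44 for E(spl) bHLH genes, 0.24 for cell cycle, -0.50 for heat shock, -0.22 for immune and Toll, -0.21 for Dpp and activin and -0.36 for insulin and growth genes.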

How the results depend on the processing

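Counts are given for DmD8, Kc, their difference and rises shared by both lines, in that order, with 938, 1542, 1415 and 78 as reported. No row could be made for the DmD8 experiment carrying the other label, for the difference or the overlap between the DmD8 experiments, since both labels hold the same values, and the difference between the lines fitted from its own experiments alone is the reported fit. Without a dye term the counts were 456, 655, 505 and 38. With each experiment fitted alone they were 552 in DmD8 and 47 shared. The replicate block, with the replicate number in place of the dye term, gave 429, 913, 608 and 39. Numbers did not pair the lines: same-numbered arrays correlated at -0.30, -0.33, 0.20, -0.13 and -0.09. Under every pairing the counts were 89, 234, 368 and 5, where fewer replicates were tested. On arrays with activated RNA in Cy5 alone, the difference fell to 183 and shared rises were 120, with 799 in DmD8 and 2070 in Kc. At an FDR under 0.01 the counts were 439, 709, 509 and 30, and with a log ratio of at least 0.5 they were 408, 501 and 28 for DmD8, Kc and shared rises. Leaving out each array gave 406 to 913, 941 to 1485, 765 to 1268 and 31 to 84. DmD8 array 4 gave the lowest of the DmD8, difference and shared counts, and shared rises were also 50 without DmD8 array 2. Without a DmD8 swap, the lone swap is assumed to vary like the other arrays. Alternatives chosen after seeing the data were swap n + 3 averaged with replicate n (173, 450, 670 and 13), Kc arrays 2 and 5 left out (899, 871 and 47 for Kc, the difference and shared rises), and the swaps turned (2211, 2592, 0 and 503, with 752 differences at an unadjusted p under 0.05 in limma). Lists past camera, 7, 8 and 6 in DmD8, Kc and their difference, were 0, 0 and 0 with an estimated correlation (6, 12 and 6 at an unadjusted p under 0.05 among 22 lists) and 13, 19 and 15 with fry. With swaps averaged, an alternative chosen after seeing the data, they were 5, 5 and 2 with camera, 0, 0 and 0 with an estimated correlation (0, 1 and 0 at an unadjusted p under 0.05) and 0, 5 and 8 with fry (7, 13 and 14 unadjusted). Apart from the construction named for pairings and single swaps, the cause was not tested. Of the named genes' values under alternatives other than leaving out an array, 1505 were called as reported (5 of the 113 results were never past the threshold and had no call to keep), 159 were no longer past the threshold and 4 turned sign: Hsc70-5 in DmD8 (0.0796, adjusted p = 0.674) and Eip93F in Kc (-0.0835) on arrays with activated RNA in Cy5, and ImpL2 in DmD8 (0.16) and RpL3 in Kc (-0.0165) with single probes. Leaving out an array lost 83 calls and turned none. No list that passed camera turned the sign of its median. Medians moved by at least 1 SD between arrays in 27 cases under the other alternatives and in 6 when an array was left out. Signal over background is not part of the values, so what it limits is unknown.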

Other observations

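The test of genes of the endoplasmic reticulum (ER) and the test of detoxification genes were set before their values were seen, on lists that leave out genes already seen. Other ER genes had by then been seen lower in DmD8. The ER list, like the detoxification list, is thus not independent of values already seen. The ER list of 26 genes, 24 of them tested, holds chaperones, disulfide isomerases and secretion genes. In DmD8, 13 of the 24 fell and none rose (median -0.34, camera in limma, adjusted p = 1.5e-10), among them the nucleotide exchange factor Sil1 (-1.17 ± 0.15), the kinase PEK (-0.78 ± 0.10), Herp (-0.78 ± 0.09), the chaperone Gp93 (-0.58 ± 0.12) and Manf (-0.54 ± 0.09). Together with Hsc70-3 (-1.02) and Ire1 (-1.14), a sensor of ER stress, they lay lower in activated than in comparison RNA. Under every pairing 1 of the 13 stayed past the threshold, and 16 of the 24 had an unadjusted p under 0.05. In Kc, 0 of the 24 passed with limma and 6 had an unadjusted p under 0.05 (median -0.0226, camera adjusted p = 0.158). At the preset correlation the list differed between the lines (median difference -0.31, camera adjusted p = 9.33e-05). With an estimated correlation of 0.111, a check added last, the DmD8 call held (adjusted p = 0.0198) and the difference was lost (adjusted p = 0.0626), both adjusted over the 6 tests of this list and the detoxification list alone; Kc gave adjusted p = 0.451. With swaps averaged the DmD8 call held at the preset correlation (adjusted p = 1.82e-07) and was lost with an estimated one (adjusted p = 0.279).

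The idea that led to this list was that P58IPK, PPP1R15, Fic and shv, which act in the ER or its stress response, had fallen in both lines (DmD8 -0.87, -0.59, -0.49 and -0.78; Kc -0.28, -0.32, -0.77 and -0.24). These genes were picked by eye from the 46 features lower in both lines, of which 0 kept both calls under every pairing with limma, where 1907 features in DmD8 and 1993 in Kc had an unadjusted p under 0.05. A fall of ER folding genes shared by both lines was a hypothesis. It needed a fall in each line. The list fell in DmD8, but in Kc 0 of the 24 passed and the median was -0.0226 (camera adjusted p = 0.158). A shared fall was thus not found. By the bounds set before it was not excluded either, since that needed a median above 0 that passed camera.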
